A study of Mus musculus with 6 samples.

How the data were processed

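RNA was sequenced from pancreatic ductal cells of 6 mice, 3 in which Pten and Brg1 were deleted (Pten_Brg1_KO, mice 6, 9 and 10) and 3 in which Pten alone was deleted (Pten_KO, mice 11, 12 and 13). Per the labels' protocols, tamoxifen was given by mouth at 6 weeks of age to switch on Hnf1b-CreERT2, a tamoxifen-dependent recombinase driven from a gene that is active in ductal cells, and the pancreas was taken 3 weeks later (day 21). The tissue was digested and ductal cells were pulled out with magnetic beads after labelling with the lectin Dolichos biflorus agglutinin. RNA was extracted with a low-input column kit and libraries were made with the SMARTer Ultra Low Input RNA kit. The labels name no molecular identifiers and do not say that the libraries keep strand.

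The authors deposited 1 table of estimated counts per gene, with 1 column per mouse, which are expected counts that need not be whole. The submitters' processing notes name Trimmomatic 0.39, STAR 2.7.3a, RSEM 1.3.1 and the build mm10, without saying what each did. The annotation release and the parameters are not given in the sources used here. The values were not scaled to depth: the column totals differed and lay between 10519773 and 11629608. Between 96.0% and 96.8% of the values in a column were whole numbers, zeros included. All 6 columns were matched to mice by the column names in the labels, and 0 columns were left unused.

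The deposited expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14246 of 55401 genes. Library sizes were scaled by the trimmed mean of M values (factors 0.900 to 1.10). Pten_Brg1_KO was compared with Pten_KO by the quasi-likelihood F-test on all 6 libraries, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Values in CPM (counts scaled to library size, edgeR cpm) are given as mean ± SD over 3 mice, and fold changes as log2(Pten_Brg1_KO / Pten_KO) ± SE from the fit. No paired analysis was possible because the groups share no mouse numbers.

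Gene symbols came from the deposited table itself, which joins each identifier to a symbol. Positions, gene types and lengths came from GENCODE M21 on GRCm38, the assembly that mm10 names. Identifiers without their version matched M21 for 55141 of the 55401 genes and 14239 of the 14246 tested ones. Transcript length is the longest annotated transcript of a gene. There were 110 repeats of a symbol already used by another gene. Of 93 named genes, 26 shared at least 1 exon base with another annotated gene, and for 11 of these the other gene was also tested.

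Before the data were examined, 28 gene lists were fixed. They held targeted genes, YAP/TAZ target genes, Hippo pathway components, SWI/SNF subunits, ductal, acinar, endocrine, immune, fibroblast and stellate, endothelial and mesothelial markers, gastric and mucinous metaplasia genes, intestinal genes, proliferation genes, epithelial-mesenchymal transition genes and laminin, integrin and plasminogen genes. They also held p53 target, FOXO target, Notch pathway, hypoxia and glycolysis, inflammatory, interferon-stimulated, immediate early and dissociation, unfolded protein response, cholesterol synthesis, primary cilium, mitochondrial encoded and sex-linked genes. Of the listed symbols, 1 was not matched to the table, and 6 tested genes were in more than 1 of the lists. The lists other than the targeted and sex-linked genes, 26 in all, were tested against the remaining genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 26. Camera with an estimated correlation and the rotation test fry were run beside it. Fry tests a list against no change, not against the remaining genes.

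The genes named were also fixed by rule before the data were examined. They were Smarca4 and Pten; the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those past the threshold, with at least 5 CPM in the higher group and all 3 libraries of one group above the 3 of the other, predicted genes (Gm numbers, names ending in Rik, clone names and -ps names) left out; and from each list up to 4 members past the threshold, smallest adjusted p first. Where fewer than 2 members passed, the 2 most abundant tested members were also named, so that a list with 1 member past the threshold could have 3 named genes. For YAP/TAZ target genes, ductal markers and proliferation genes up to 3 further members with the highest mean CPM were named whether they passed or not. Yap1, Wwtr1, Smarca2, Ccn1 and Ccn2 were named in any case. Genes outside this rule are said to be chosen after their values were seen.

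Measures of whole libraries were compared with a two-sided exact permutation test of the 3 against 3 mice, which cannot give a p below 0.1. Shares of counts have Wilson 95% intervals. Where a group held 1 to 3 counts of a gene in total, the ratio is given from total counts scaled to depth, with an exact binomial 95% interval. A total of 3 counts in 1 library corresponded to between 0.258 and 0.285 CPM without the scaling factors. These are PCR-amplified reads without molecular identifiers, so intervals and floors cover counting error only.

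The alternatives fixed before the data were examined were the RLE and upper-quartile normalizations, no filter on low counts, at least 5 CPM in 3 libraries, limma-voom with and without sample quality weights, DESeq2 1.42.0, robust dispersion estimation, a test against a fold of 1.5, unrounded counts, the removal of acinar, endocrine and mitochondrial list genes, and leaving out each mouse in turn. Alternatives chosen after seeing the data were an offset that removes, in each library, a smooth trend (natural spline, 5 degrees of freedom) of log2 CPM (pseudocount 2) on transcript length, the same with GC content, leaving out mice 6 and 13 together, and the acinar marker mean as a covariate.

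The tests were tested on simulated data, drawn for the real genes and library sizes at 3 against 3, with 200 genes changed by known folds. With no length trend, 21.0% of the 2-fold and 83.0% of the 4-fold changes were recovered over 14022 genes, and 7 of 111 calls were false. With the length slopes of the real libraries added, 46 of 150 calls were false over 14014 genes without the offset and 5 of 103 with it. A list of 35 proliferation genes simulated 2-fold higher passed, and 0 of the 25 other lists did. That simulation drew genes independently and held no length trend. It therefore does not show how often lists of correlated genes pass falsely at the preset correlation.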

Results

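The data were RNA-seq counts from pancreatic ductal cells of 6 mice at day 21 after tamoxifen. In 3 mice both Pten, a phosphatase that opposes PI3K signalling, and Brg1, an ATPase of the SWI/SNF chromatin remodelling complexes encoded by Smarca4, were deleted. In the other 3 mice Pten alone was deleted. The comparison asked what the deletion of Brg1 changed in ductal cells in which Pten was deleted as well, and the series names the YAP/TAZ pathway, which drives transcription when Hippo signalling is low. No mice with intact Pten were part of the series. Total counts were 11629608, 10870934 and 10993004 in Pten_Brg1_KO mice 6, 9 and 10, and 11281014, 10519773 and 11026755 in Pten_KO mice 11, 12 and 13. Between 18738 and 20034 genes had at least 1 count in a library.

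Smarca4 (ENSMUSG00000032187.16; mm10 chromosome 9, 21616169 to 21704230, plus strand, protein-coding) was lower in every Pten_Brg1_KO library than in every Pten_KO library. It stood at 34.3, 31.4 and 31.8 CPM in Pten_Brg1_KO mice 6, 9 and 10, and at 75.6, 73.1 and 98.7 CPM in Pten_KO mice 11, 12 and 13. The means were 32.5 ± 1.57 and 82.5 ± 14.1 CPM (SD, n = 3 each), a 2.54-fold lower level (log2 fold change -1.34 ± 0.18 SE, edgeR adjusted p = 0.029). Smarca4 transcript thus remained at more than a trace in the deleted group; the counts are per gene and do not separate transcripts of a recombined allele from intact ones. Pten (ENSMUSG00000013663.7; chromosome 19, 32757497 to 32826160, plus strand, protein-coding), deleted in both groups, stood at 46.0, 51.0 and 43.5 CPM in Pten_Brg1_KO and at 79.8, 69.7 and 122 CPM in Pten_KO (log2 fold change -0.95 ± 0.23, edgeR adjusted p = 0.066). DESeq2 called Pten lower, and with the length offset its log2 fold change was -0.49 and did not pass. Pten transcript was thus present in all 6 libraries, with no mice with intact Pten to set it against. The Smarca4 call depended on which mice were included: the adjusted p was 0.074 without mouse 6, 0.119 without mouse 9, 0.102 without mouse 10, 0.021 without mouse 11, 0.087 without mouse 12 and 0.060 without mouse 13, and over all alternatives it ran from 9.4e-07 to 0.445. Among the 500 protein-coding genes closest to Smarca4 in transcript length, whose median log2 fold change was -0.41, 18 were as low or lower.

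**Figure D1:**
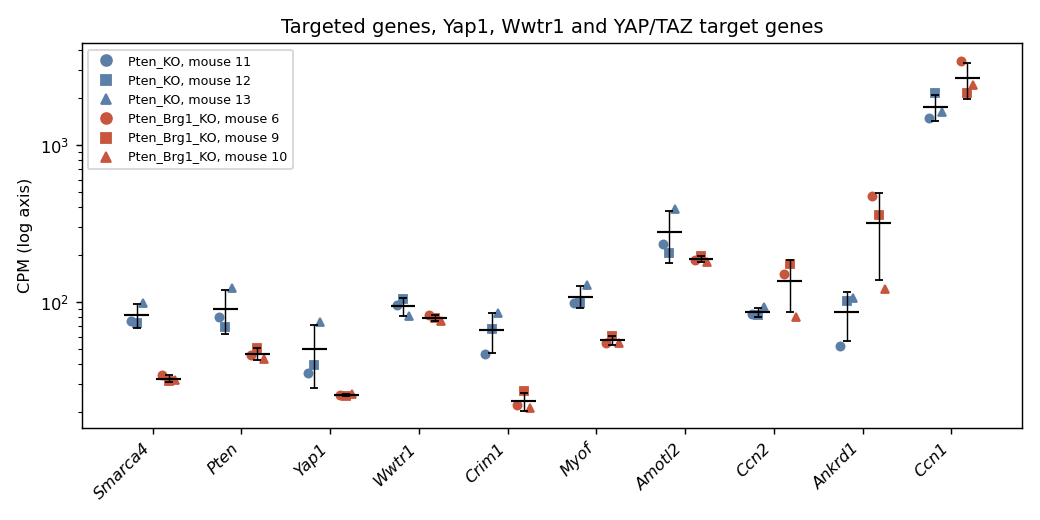
CPM on a log axis for the targeted genes, Yap1, Wwtr1 and 6 YAP/TAZ target genes; each symbol is 1 mouse, horizontal bars are means and whiskers are SD over 3 mice. Smarca4 lay between 31.4 and 34.3 CPM in Pten_Brg1_KO and between 73.1 and 98.7 CPM in Pten_KO, while Ccn1, Ccn2 and Ankrd1 had higher means in Pten_Brg1_KO and Crim1 and Myof lower ones.

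Across the transcriptome 324 genes passed, 91 higher and 233 lower in Pten_Brg1_KO. Of all 14246 tested genes 3937 had an unadjusted p under 0.05 in edgeR. Counts at that limit in the gene lists below are to be read against this share. The higher genes with the largest changes included Lyve1, a hyaluronan receptor of lymphatic endothelium and some macrophages, and Vsig4, a complement receptor of resident macrophages. Lyve1 stood at 148 ± 48.0 against 17.7 ± 8.81 CPM (log2 fold change 3.06 ± 0.42, adjusted p = 0.032), and Vsig4 at 9.12 ± 3.33 against 0.895 ± 0.756 CPM (3.34 ± 0.62, adjusted p = 0.041). Fbp1, a gluconeogenic enzyme, was at 22.8 ± 9.85 against 0.985 ± 0.510 CPM, Ubash3b, a tyrosine phosphatase, at 25.6 ± 3.60 against 1.87 ± 0.629 CPM, and Ceacam20, a cell adhesion molecule, at 45.3 ± 15.9 against 4.42 ± 2.40 CPM. Fxyd2, a subunit of the sodium pump, and Zfp691, a zinc finger gene, had log2 fold changes of 2.89 ± 0.53 and 2.96 ± 0.39. Fhl3, a LIM domain gene, had 224 counts in all Pten_Brg1_KO libraries and 3 in all Pten_KO libraries, a depth-scaled ratio of 73.2 (exact binomial 95% interval 24.7 to 358). Rn7s2, a short non-coding RNA with many genomic copies, and Amy2b, an amylase gene that M21 lists as an unprocessed pseudogene beside close paralogs, were also among the 10 highest; their counts are uncertain because reads could be split between copies.

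The lower genes with the largest changes had varied known functions. Gabrp, a GABA receptor subunit, stood at 18.7 ± 4.95 in Pten_Brg1_KO against 164 ± 112 CPM in Pten_KO, and Lamb3, a chain of the basement membrane protein laminin-332, at 13.1 against 86.4 CPM (log2 fold change -2.73 ± 0.44). Ildr2, a membrane protein gene, was at 3.90 against 39.5 CPM (-3.34 ± 0.40), Mgat3, a glycosyltransferase, at 3.14 ± 0.766 against 25.8 ± 12.5 CPM, and Shisa2 at 2.82 ± 1.08 against 25.6 ± 22.7 CPM. Slc5a9, a sugar transporter, and Ugt2b34, one of a family of similar glucuronosyltransferases, had log2 fold changes of -3.96 ± 0.72 and -3.37 ± 0.66. Cep85 (chromosome 4, 134129858 to 134187112, minus strand), a centrosomal gene, had the smallest adjusted p of all genes: it stood at 12.2 ± 2.29 against 157 ± 31.6 CPM (log2 fold change -3.69 ± 0.24, adjusted p = 0.0027). Rab6b, a small GTPase of Golgi traffic, had 2 counts in all Pten_Brg1_KO libraries and 584 in all Pten_KO libraries, a depth-scaled ratio of 298 (exact binomial 95% interval 82.1 to 2466). Adnp, a chromatin-associated homeobox gene, was at 7.06 ± 4.96 against 65.9 ± 26.5 CPM; this is uncertain, because Adnp shares up to 4187 bases of an exon with the same-strand gene Gm20716, which stood at 29.4 and 18.4 CPM.

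In all 324 genes the 3 libraries of one group lay above the 3 of the other. Of all tested genes 35.0% did so, where 10% is the average over all splits into 3 and 3. The libraries varied along 1 main axis (50.9% of the variance), so many genes can separate together. The 2 shares therefore do not show a genotype effect. The number of genes called depended on single mice. It was 15 without mouse 6, 7 without mouse 9 and 6 without mouse 10. It was 1374 without mouse 11, 13 without mouse 12 and 7 without mouse 13. Of the 34 named genes that passed, Cep85, Rab6b and Ubash3b passed in all 6 of these fits, and between 3 and 33 did in each. Ubash3b and Cep85 lie in the regions of chromosomes 9 and 4 where calls clustered, as described at the end. Whether DNA that differs between the mice causes those calls was not settled. DESeq2 called 1665 genes, among them 323 of the 324. A length offset, chosen after seeing the data, left 80 genes, 36 higher and 44 lower, of which 73 were among the 324. Of the 34 named genes that passed, 16 did so with the offset. For Amy2b, Vsig4, Fxyd2, Slc5a9, Ugt2b34, Shisa2, Gabrp, Upk3b and Dll1, which did not, the log2 fold change with the offset was between 88.0% and 101% of that without it. The call ended there as the adjustment became stricter: the largest unadjusted p among called genes was 0.00113 without and 2.7e-04 with the offset, in edgeR fits over all 14246 genes. Lrrn4 kept 98.5% of its log2 fold change and missed both limits (unadjusted p = 0.00116 with the offset, edgeR over all genes). Crim1, Myof, Mob1b, Smarcc1, Mfap4, Lamb1, Lama3 and Bax did not pass with the offset either. Of their log2 fold changes 38.7% to 84.6% remained. For Crim1, Smarcc1, Mfap4, Lamb1 and Lama3 the unadjusted p with the offset (edgeR) was still under 0.00113. Their calls therefore also ended with the stricter adjustment, unlike those of Myof, Mob1b and Bax.

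**Figure D2:**
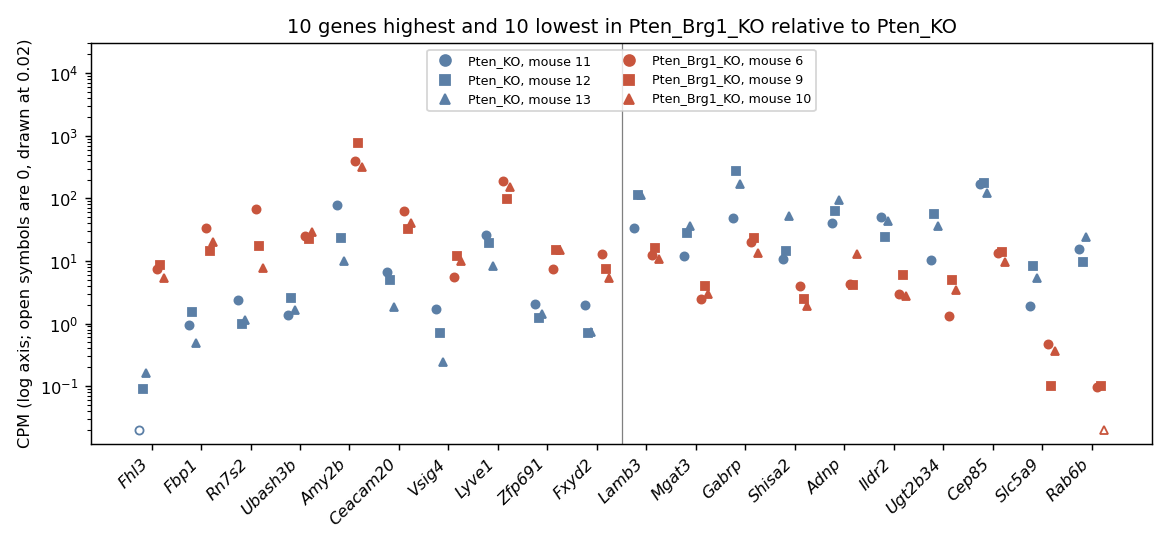
CPM on a log axis for the 10 genes with the largest positive (left) and the 10 with the largest negative (right) log2 fold change among those past the threshold; each symbol is 1 mouse, and open symbols are libraries with 0 counts. The 3 mice of one genotype lay above the 3 of the other for all 20 genes, which the selection rule required.

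The YAP/TAZ target genes did not move in 1 direction as a set. Of 22 tested targets edgeR called 0 higher and 2 lower, DESeq2 1 higher and 4 lower and limma-voom 2, and 9 had an unadjusted p under 0.05. Those that fell in edgeR were Crim1, a membrane-bound BMP antagonist, from 66.3 ± 19.0 to 23.4 ± 3.09 CPM (log2 fold change -1.50 ± 0.24, adjusted p = 0.037), and Myof, a membrane repair gene, from 108 ± 17.4 to 56.9 ± 3.53 CPM (-0.93 ± 0.17, adjusted p = 0.041). Neither passed with the length offset, where their log2 fold changes were -1.15 ± 0.20 and -0.52 ± 0.15. Adjusted over the list alone, 1 was higher and 4 were lower. Ccn1 and Ccn2, matricellular genes that are widely used readouts of YAP, did not pass, with log2 fold changes of 0.60 ± 0.30 (adjusted p = 0.222) and 0.65 ± 0.27 (adjusted p = 0.170). Ankrd1, another such readout, stood at 318 ± 180 against 86.5 ± 29.8 CPM (1.88 ± 0.48, edgeR adjusted p = 0.073) and was the 1 target that DESeq2 called higher, and Amotl2 at 187 ± 8.32 against 277 ± 100 CPM (adjusted p = 0.192). When 1 mouse was left out, Ccn1 ran from 0.38 to 0.77, Ccn2 from 0.42 to 0.92 and Amotl2 from -0.74 to -0.22, never past the threshold. The list median was -0.21 (camera adjusted p = 0.226) and 0.011 with the length offset. With the offset Ccn1, Ccn2 and Ankrd1 had log2 fold changes of 0.32, 0.50 and 1.57, none past the threshold. In the fry test of change in either direction, run without the offset, the list passed (adjusted p = 0.020). It was 1 of 13 among the 26 lists that did. Fry does not compare a list with the remaining genes, and fold changes followed transcript length over all genes. The fry result therefore does not single out the YAP/TAZ targets.

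Genes of the Hippo pathway itself were lower as a set. The median of the 24 tested components was -0.53, and 22 of them had negative log2 fold changes (camera adjusted p = 2.1e-04; adjusted p = 0.669 with an estimated correlation). One component passed in edgeR, while DESeq2 called 5 lower and limma-voom 0, and 11 had an unadjusted p under 0.05. It was Mob1b, a cofactor of the LATS kinases, which fell from 29.5 ± 7.88 to 12.6 ± 1.63 CPM (adjusted p = 0.044), and 9 were lower adjusted over the list alone. Yap1 stood at 25.4, 25.1 and 25.9 CPM in Pten_Brg1_KO and at 35.4, 39.7 and 74.8 CPM in Pten_KO (log2 fold change -0.97 ± 0.28, edgeR adjusted p = 0.093). DESeq2 called Yap1 lower; in edgeR its log2 fold change was -1.16 and passed without mouse 11, and was -0.55 and did not pass without mouse 13. Wwtr1, which encodes TAZ, had a log2 fold change of -0.25 ± 0.16 (adjusted p = 0.339), and Wwc1 one of -0.86 ± 0.40 (adjusted p = 0.199), which was -0.20 without mouse 13. These were long genes, with a median transcript length of 4709 bases against 3247 over all tested genes, and with the length offset the list median was -0.30, Mob1b had a log2 fold change of -0.75 ± 0.21 and no component passed. The list as a set passed with the offset (camera adjusted p = 0.021, over its alternatives 1.8e-06 to 0.669; adjusted p = 0.621 with an estimated correlation).

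Among SWI/SNF subunits, Smarcc1, a core scaffold subunit, fell beside Smarca4, from 87.9 ± 24.6 to 35.7 ± 2.32 CPM (log2 fold change -1.30 ± 0.22, adjusted p = 0.039). With the length offset Smarcc1 had a log2 fold change of -0.96 ± 0.19 and did not pass, while Smarca4 did. Smarca2, the paralogous ATPase, stood at 90.6 ± 10.6 against 137 ± 29.5 CPM (-0.60 ± 0.20, adjusted p = 0.118). Of 26 tested subunits edgeR called 0 higher and 2 lower, DESeq2 1 higher and 4 lower and limma-voom 2, and 9 had an unadjusted p under 0.05; 1 was higher and 3 were lower adjusted over the list alone. The median was -0.17 (camera adjusted p = 0.119).

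The most abundant ductal identity genes stayed at high levels in both groups. Spp1 was at 26945 ± 2011 against 14628 ± 4541 CPM (edgeR adjusted p = 0.193), and DESeq2 called it higher (adjusted p = 0.010). Clu, Krt8, Krt18 and Cdh1 had log2 fold changes of 0.20, 0.26, 0.36 and -0.55, none past the threshold in edgeR or DESeq2. Aqp1, a water channel of small ducts, was the 1 of 34 tested markers that passed in edgeR (DESeq2 called 3 higher and 5 lower) and fell from 147 ± 48.3 to 27.1 ± 11.9 CPM (log2 fold change -2.44 ± 0.37, adjusted p = 0.033). Adjusted over the list alone, 1 was higher and 5 were lower. The list median was 0.085 and its mean -0.14 (camera adjusted p = 0.383, direction down). With the length offset the median was -0.16 and the list passed (camera adjusted p = 0.034, and 0.687 with an estimated correlation). It was also 1 of 13 among the 26 lists that passed the fry test of change in either direction (adjusted p = 0.0075).

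Basement membrane and integrin genes were lower as a set. Of 23 tested laminin, integrin and plasminogen genes edgeR called 3 lower and 0 higher, DESeq2 9 lower and 0 higher and limma-voom 1, and 14 had an unadjusted p under 0.05; 12 were lower adjusted over the list alone, and 20 had negative log2 fold changes. The median was -0.75 (camera adjusted p = 1.9e-06; adjusted p = 0.669 with an estimated correlation). Beside Lamb3, the other chains that passed were Lamb1, which fell from 76.8 ± 21.7 to 31.9 ± 1.19 CPM, and Lama3, which fell from 11.2 ± 5.67 to 1.70 ± 0.277 CPM (adjusted p = 0.040 for both). The median transcript length of these genes was 5784 bases, and with the length offset the list median was -0.50 and Lamb3 alone passed, while the list as a set passed (camera adjusted p = 4.5e-04, over its alternatives 1.9e-10 to 0.669; adjusted p = 0.621 with an estimated correlation). In the Notch pathway the ligand Dll1 fell from 30.8 ± 10.95 to 8.82 ± 3.00 CPM (adjusted p = 0.044), 1 of 19 tested genes in edgeR (DESeq2 called 5 lower and limma-voom 0); 5 were lower adjusted over the list alone. Hes1 and Hes6, Notch-responsive and related repressors, had log2 fold changes of 0.23 ± 0.42 and 0.18 ± 0.18, and the list median was -0.25 (camera adjusted p = 0.101).

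**Figure D3:**
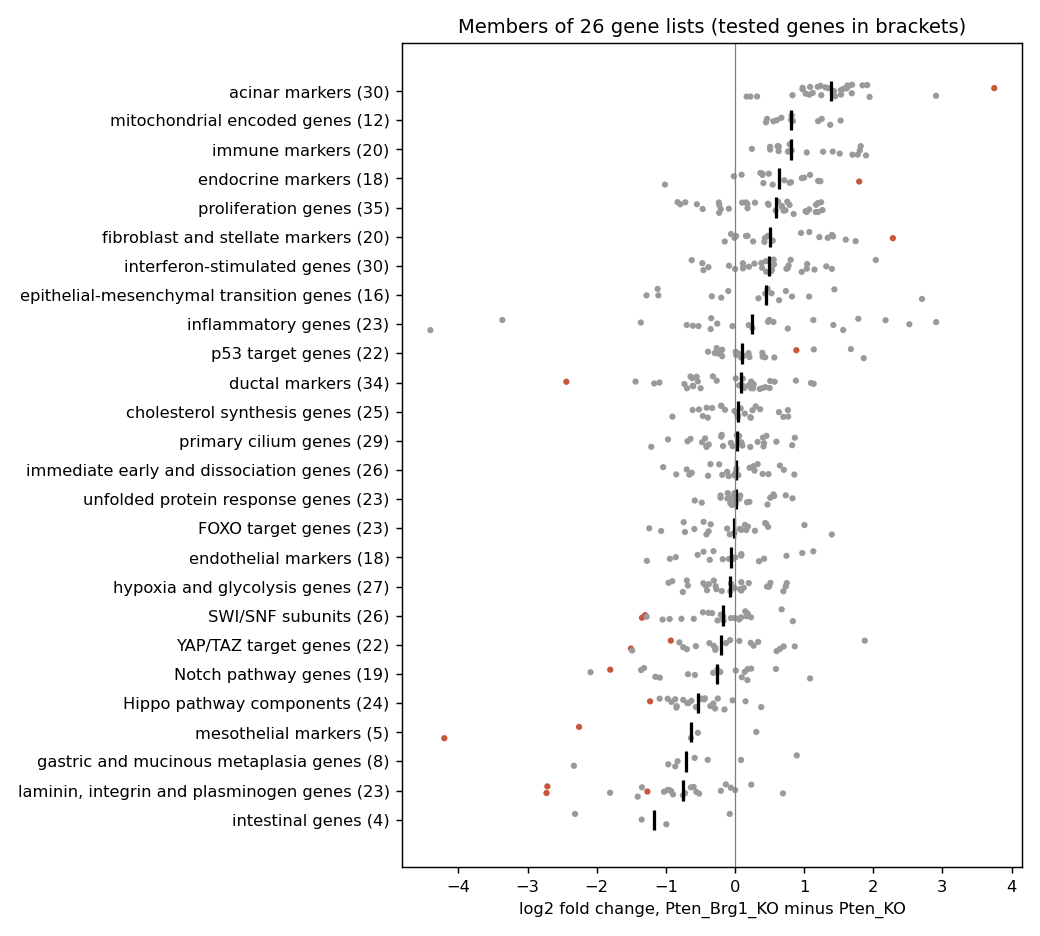
Log2 fold change (Pten_Brg1_KO minus Pten_KO) of each tested member of 26 gene lists, 1 point per gene, with members past the threshold in red and the list median as a black bar. Acinar markers had a median of 1.39 and laminin, integrin and plasminogen genes one of -0.75, while the YAP/TAZ target genes spread on both sides of 0.

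Markers of pancreatic cell types other than duct differed between the groups. All 30 acinar markers, most of them digestive enzymes, had positive log2 fold changes with a median of 1.39 (camera adjusted p = 1.4e-09; adjusted p = 0.669 with an estimated correlation). In edgeR Amy2b alone passed, over all genes and adjusted over the list alone, while DESeq2 called Amy2b and Try4 higher. Without mouse 11 the median was 2.29. Cela2a, which shares exon bases with the acinar gene Ctrc, and Try4, one of the trypsin paralogs, stood at 15772 ± 5180 against 5844 ± 5030 CPM and 15470 ± 3974 against 4944 ± 3577 CPM. The acinar list took 13.3%, 15.2% and 9.65% of the counts in Pten_Brg1_KO mice 6, 9 and 10, and 9.56%, 5.04% and 1.24% in Pten_KO mice 11, 12 and 13 (exact permutation p = 0.1, adjusted p = 0.4 over 12 library measures; 0.1 is the smallest p that 3 against 3 can give). Ductal markers took 5.55 ± 0.34% against 4.82 ± 0.077% (exact permutation p = 0.1, adjusted p = 0.4).

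All 20 tested immune markers had positive log2 fold changes, with a median of 0.81 (camera adjusted p = 3.3e-04; adjusted p = 0.669 with an estimated correlation). None passed in edgeR, 7 had an unadjusted p under 0.05, DESeq2 called 4, limma-voom 0, and 4 were higher adjusted over the list alone. Lyz2, the macrophage lysozyme, stood at 2264 ± 973 against 792 ± 336 CPM (adjusted p = 0.093) and Cd74 at 972 ± 980 against 633 ± 168 CPM (adjusted p = 0.539). As shares of counts immune markers overlapped between the groups, at 1.08%, 0.484% and 0.367% in mice 6, 9 and 10 against 0.399%, 0.411% and 0.212% in mice 11, 12 and 13 (exact permutation p = 0.3, adjusted p = 0.6 over 12 library measures). The immune median was 1.28 without mouse 9 and 1.26 without mouse 10. Without mouse 6 it was 0.24 and the list did not pass (camera adjusted p = 0.160; over its alternatives 1.7e-08 to 0.834). Fibroblast and stellate markers had a median of 0.51 (camera adjusted p = 5.7e-04; adjusted p = 0.669 with an estimated correlation). DESeq2 called 6 of the 20 tested higher and limma-voom 0. In edgeR Mfap4, a matrix glycoprotein, rose from 3.99 ± 1.87 to 19.4 ± 7.60 CPM (adjusted p = 0.041), and 3 were higher adjusted over the list alone; Gsn and Col3a1 had log2 fold changes of 0.47 ± 0.20 and 0.43 ± 0.44. The list median was 0.82 without mouse 10, and without mouse 6 it was 0.23 and the list did not pass.

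Endocrine markers had a median of 0.63 (camera adjusted p = 0.00999; adjusted p = 0.669 with an estimated correlation). DESeq2 called 3 of the 18 tested higher and 1, Slc2a2, lower. The 1 that rose in edgeR was Mafb, a transcription factor of alpha cells and of macrophages, from 32.3 ± 6.82 to 112 ± 35.5 CPM (adjusted p = 0.033); adjusted over the list alone 3 were higher and 1 lower. Ttr and Slc2a2 had log2 fold changes of 0.40 ± 0.28 and -1.01 ± 0.24. The list median was 0.32 with the length offset, and the list did not pass with it or without mouse 6, where the median was 0.23; without mouse 11 the median was 0.9997. Mesothelial markers, of which 5 were tested, had a median of -0.64 (camera adjusted p = 0.030; adjusted p = 0.669 with an estimated correlation). In edgeR Upk3b fell from 24.1 ± 7.97 to 5.05 ± 2.46 CPM (adjusted p = 0.040), and Lrrn4 had 48 counts in Pten_KO and 2 in Pten_Brg1_KO, a depth-scaled ratio of 24.5 (exact binomial 95% interval 6.42 to 208; adjusted p = 0.049). Both also passed adjusted over the list alone, limma-voom called both and DESeq2 called Upk3b. The list median was -1.29 without mouse 9, -1.06 without mouse 11, -0.54 without mouse 6 and -0.11 without mouse 12, and the list did not pass in the last 2 cases. The log2 fold change of Lrrn4 was -6.95 without mouse 6 against -4.20 with all mice. Endothelial markers did not differ as a set (18 tested, 0 past the threshold in edgeR and limma-voom, 1 in DESeq2, 2 at an unadjusted p under 0.05, median -0.060, camera adjusted p = 0.969). Their most abundant members Plvap and Egfl7 had log2 fold changes of 0.092 and 0.091, which were -0.17 and -0.21 with the length offset.

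**Figure D4:**
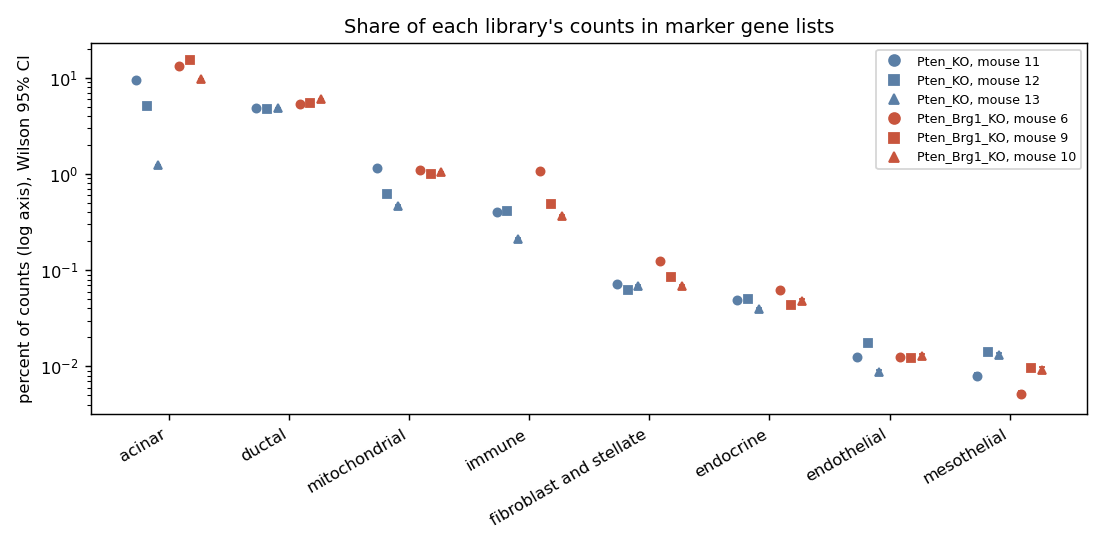
Share of each library's counts in 8 marker lists, in percent on a log axis; each symbol is 1 mouse and whiskers are Wilson 95% intervals, mostly smaller than the symbols. The acinar share ran from 9.65% to 15.2% in Pten_Brg1_KO and from 1.24% to 9.56% in Pten_KO, while the ductal share lay between 4.73% and 5.94% in all 6.

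Proliferation genes did not differ past the threshold (35 tested, 0 past it in edgeR and limma-voom, 2 in DESeq2, 7 at an unadjusted p under 0.05). Their median was 0.59 (camera adjusted p = 0.14), and it was -0.14 without mouse 6. The list passed, higher, without mouse 9, without mouse 10, without mouse 12 and with the acinar covariate. The replication genes Mcm6, Pcna, Mcm7, Rrm1 and Mcm4 had log2 fold changes of -0.47, 0.16, -0.23, -0.79 and -0.72. Gastric and mucinous metaplasia genes (8 tested, median -0.71, camera adjusted p = 0.246) and intestinal genes (4 tested, median -1.17, camera adjusted p = 0.101) had 0 members past the threshold in edgeR and limma-voom, 1 each in DESeq2 and 2 each at an unadjusted p under 0.05; adjusted over the list alone, 1 and 2 were lower. Tff2 stood at 82.0 ± 46.2 against 44.1 ± 29.0 CPM, Creb3l1 at 57.8 ± 14.2 against 54.4 ± 18.3 CPM, Olfm4 at 20.0 ± 3.91 against 99.6 ± 98.0 CPM and Lgals4 at 18.0 ± 6.30 against 19.0 ± 5.43 CPM. Among epithelial-mesenchymal transition genes (16 tested, median 0.46, camera adjusted p = 0.14), 0 passed in edgeR and limma-voom, 6 in DESeq2 and 6 at an unadjusted p under 0.05, and 3 were higher and 2 lower adjusted over the list alone. Sparc and Mmp14 had log2 fold changes of 0.44 ± 0.24 and -0.10 ± 0.27.

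Of the p53 targets, the pro-apoptotic gene Bax rose from 47.3 ± 6.32 to 87.5 ± 8.30 CPM (adjusted p = 0.043), 1 of 22 tested in edgeR (DESeq2 called 4 higher and limma-voom 1), and 3 were higher adjusted over the list alone. Btg2 and Plk2 had log2 fold changes of 0.049 ± 0.30 and 0.40 ± 0.21, and the list median was 0.11 (camera adjusted p = 0.162). Bax has a transcript of 1100 bases and a log2 fold change of 0.89 ± 0.17, which was 0.34 with the length offset. FOXO targets, which PI3K signalling represses, had a median of -0.011 (23 tested, camera adjusted p = 0.833), with 0 past the threshold in edgeR and limma-voom, 5 in DESeq2 and 6 at an unadjusted p under 0.05; 1 was higher and 3 were lower adjusted over the list alone. Klf6 and Txnip had log2 fold changes of -0.011 and -0.11; the direction of Klf6 flipped under the RLE and upper-quartile normalizations.

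The remaining stress and metabolic lists did not pass in the main camera test. Hypoxia and cilium genes were among the 13 of 26 lists that passed the fry test of change in either direction (adjusted p = 0.028 for both). Hypoxia and glycolysis genes had a median of -0.066 (27 tested, Aldoa being on 2 gene identifiers; camera adjusted p = 0.451), inflammatory genes 0.25 (23 tested, 0.517), interferon-stimulated genes 0.49 (30 tested, 0.062) and immediate early and dissociation genes 0.011 (26 tested, 0.875). Unfolded protein response genes had a median of 0.010 (23 tested, 0.693), cholesterol synthesis genes 0.040 (25 tested, 0.517) and primary cilium genes 0.026 (29 tested, 0.875). In these 7 lists edgeR and limma-voom called 0 members, over all genes tested. In the same order, DESeq2 called 4, 5, 5, 0, 0, 3 and 4. An unadjusted p under 0.05 in edgeR was found for 9, 7, 9, 3, 3, 5 and 8. Over all 14246 tested genes it was found for 3937. Adjusted over the list alone, 1 cilium gene was higher and no member of the others passed. The interferon list passed in camera with no filter on low counts and without mouse 9, 10 or 12. Inflammatory genes passed without mouse 10 and cholesterol synthesis genes with the acinar covariate. Immediate early and dissociation genes passed, lower, without mouse 6 (median -0.19, camera adjusted p = 0.018). The abundant members Eno1 and Aldoa stood at 1455 ± 45.9 against 1515 ± 335 CPM and 834 ± 84.9 against 783 ± 159 CPM, Nfkbia and Nfkbiz at 699 ± 416 against 412 ± 51.6 CPM and 412 ± 288 against 526 ± 161 CPM, and H2-D1 and H2-K1 at 1944 ± 540 against 1689 ± 781 CPM and 1070 ± 246 against 631 ± 253 CPM. Fos and Egr1, which respond to tissue dissociation, were at 6617 ± 1133 against 7046 ± 768 CPM and 5498 ± 1170 against 5462 ± 1076 CPM. Hspa5, Herpud1, Fdft1 and Srebf2 had log2 fold changes of -0.067, 0.035, 0.25 and 0.14. The cilium genes Pkd2 and Pkhd1 stood at -1.21 ± 0.39 (adjusted p = 0.110) and -0.64 ± 0.17 (adjusted p = 0.079) on the same scale. The Pkd2 value ran from -1.48 to -0.56 when 1 mouse was left out. Of 4 tested sex-linked genes 0 passed in edgeR, DESeq2 and limma-voom and 1 had an unadjusted p under 0.05; the Y-linked Eif2s3y and Ddx3y had lowest values of 36.7 and 32.9 CPM over the 6 libraries.

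The mitochondrial encoded genes had positive log2 fold changes in all 12 tested members, but their shares of counts overlapped between the groups. They took 1.098%, 1.005% and 1.049% of the counts in Pten_Brg1_KO mice 6, 9 and 10, and 1.141%, 0.614% and 0.468% in Pten_KO mice 11, 12 and 13, with mouse 11 the highest of all 6 (exact permutation p = 0.4, adjusted p = 0.655 over 12 library measures). The median log2 fold change was 0.82 (camera adjusted p = 5.5e-04; adjusted p = 0.669 with an estimated correlation). No member passed in edgeR or limma-voom, 1 in DESeq2 and 3 at an unadjusted p under 0.05, and 0 adjusted over the list alone. Transcripts of mt-Co1 and mt-Cytb stood at 2865 ± 422 against 2077 ± 1151 CPM and 2743 ± 239 against 1563 ± 764 CPM. The list median was 1.28 without mouse 11. With the length offset it was 0.28 and the list did not pass, while with the length and GC offset it was 0.36 and the list passed. For the 8 lists that passed, the adjusted p over all alternatives ran from 2.6e-16 to 0.834.

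Fold changes followed transcript length. Over 13036 protein-coding genes Spearman's rho of length and log2 fold change was -0.52, a correlation across genes, which are not independent replicates. The shortest eighth (204 to 1588 bases) had a median log2 fold change of 0.54 and the longest (6300 bases or more) one of -0.48. Of the 233 lower genes 125 were in the longest eighth, and the median length was 6561 bases for the lower and 2341 bases for the higher genes. The slope of log2 CPM per doubling of length, relative to each gene's mean, was -0.31, -0.13 and -0.096 in Pten_Brg1_KO mice 6, 9 and 10 and 0.054, 0.18 and 0.30 in Pten_KO mice 11, 12 and 13 (exact permutation p = 0.1, adjusted p = 0.4). Libraries also lay along one main axis, with mouse 6 at one end and mouse 13 at the other of a first principal component that held 50.9% of the variance. Correlations of log2 CPM ran from 0.945 to 0.978 within groups and from 0.875 to 0.961 between them, and no pair of libraries agreed within sampling noise (chi-square per degree of freedom 28.9 or more).

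**Figure D5:**
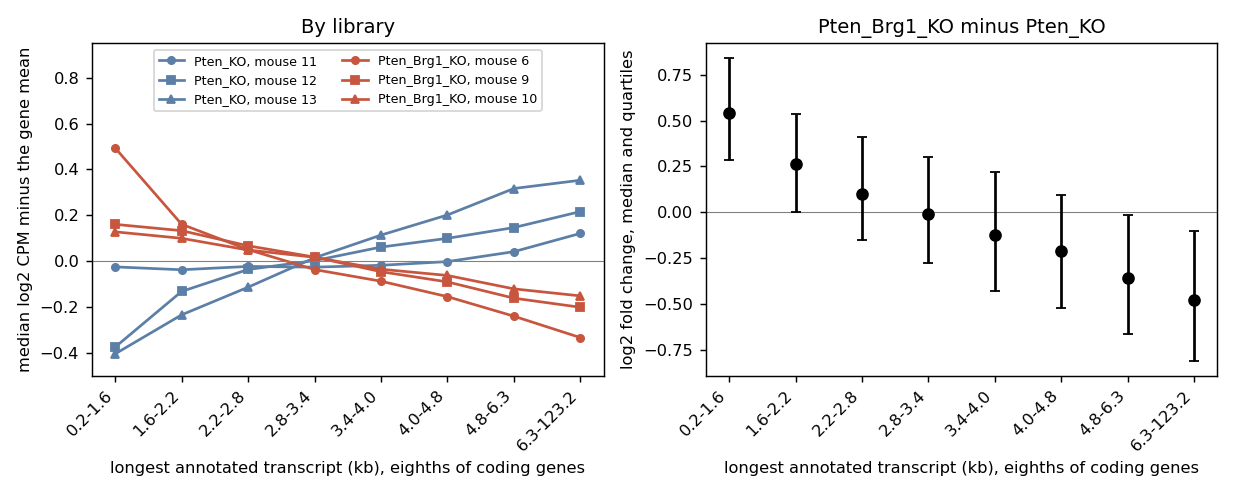
Left: median deviation of log2 CPM from each gene's mean over the 6 libraries, by eighths of longest annotated transcript length in kilobases, 1 line per mouse. Right: median log2 fold change (Pten_Brg1_KO minus Pten_KO) with quartiles as whiskers in the same eighths, falling from 0.54 in the shortest to -0.48 in the longest.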

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

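The length offset, the length and GC offset, leaving out mice 6 and 13 together and the acinar covariate were chosen after seeing the data. The genes changed, 324 in edgeR, numbered 303 to 326 under both other normalizations, the stricter filter, robust dispersion, unrounded counts and without acinar, endocrine and mitochondrial genes, and 217 in limma-voom. They numbered 877 with no filter on low counts (23791 genes tested), 816 with sample quality weights in limma-voom, 1665 in DESeq2, 9 against a fold of 1.5, 80 with the length offset, 82 with length and GC, 7 without mice 6 and 13 and 1 with the acinar covariate, and 6 to 1374 when 1 mouse was left out. The acinar share was higher in every Pten_Brg1_KO library (9.65% to 15.2%) than in every Pten_KO library (1.24% to 9.56%). The acinar covariate can therefore not be told apart from genotype. Fewer calls with it do not show that acinar content is the cause. The share of lower genes went from 71.9% to 55.0% with the length offset. All 324 kept their direction in each of these fits that held them. For Smarca4 the log2 fold change kept its sign and lost the threshold without mice 6 and 13 (-1.24) and with the acinar covariate (-1.08), and ran from -1.43 to -1.19 when 1 mouse was left out. Smarca4 also missed the threshold in the edgeR test against a fold of 1.5 (adjusted p = 0.112). The gene lists past the threshold, 8 with the preset correlation, numbered 0 with an estimated correlation, 0 in fry (13 in its test of change in either direction), 4 without mice 6 and 13, 5 with the acinar covariate and 5 to 15 when 1 mouse was left out. Hippo, acinar, laminin and mitochondrial lists passed in all 6 of the latter. Those 13 in fry were the YAP/TAZ target, Hippo, SWI/SNF, ductal, endocrine, mesothelial, transition, laminin, p53, FOXO, Notch, hypoxia and cilium lists. The acinar, immune, fibroblast and mitochondrial lists, which passed in camera, were not among them. Apart from fewer mice or more genes tested, the causes were not tested.

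Directions turned in these cases, given as log2 values or list medians. Named genes other than Smarca4 were followed only with RLE, upper quartile, limma-voom, DESeq2, the length offset and a single mouse left out. For those below the threshold, the direction in the other fits was not examined, so turns listed there are of lists only. RLE: Klf6 0.0057 and FOXO targets 0.0057. Upper quartile: Klf6 0.038 and FOXO targets 0.038. Stricter filter: endothelial 0.11, FOXO 0.012, inflammatory -0.016. Limma-voom: endothelial 0.0022, immediate early and dissociation genes -0.047. Length offset: Clu -0.13, Krt8 -0.037, Krt18 -0.092, Ttr -0.14, Plvap -0.17, Egfl7 -0.21, Creb3l1 -0.039, Pcna -0.29, Btg2 -0.042, Klf6 0.15, Hes1 -0.23, Hes6 -0.22, Aldoa -0.28, H2-D1 -0.055, Hspa5 0.0020, Herpud1 -0.21, YAP/TAZ targets 0.011, ductal -0.16, FOXO 0.045, immediate early -0.31 and unfolded protein response -0.038. Length and GC: ductal -0.18, FOXO 0.033, immediate early -0.18, unfolded protein response genes -0.034. Mice 6 and 13 left out: SWI/SNF 0.055, proliferation -0.075, inflammatory -0.37, interferon -0.17, immediate early -0.18, unfolded protein response genes -0.021. Acinar covariate: SWI/SNF 0.082, acinar -0.14, unfolded protein response -0.060, primary cilium genes -0.0050, mitochondrial -0.012. That covariate is the mean of the acinar markers themselves, so a value near 0 for the acinar list follows from the fit.

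With 1 mouse left out the ranges that crossed 0 were Cd74 -0.63 to 1.03, Col3a1 -0.29 to 0.79, Lgals4 -0.40 to 0.15, Pcna -0.14 to 0.34, Mmp14 -0.28 to 0.23, Btg2 -0.10 to 0.22, Txnip -0.49 to 0.28, H2-D1 -0.044 to 0.64, Egr1 -0.14 to 0.17, Klf6 -0.22 to 0.097, Fos -0.22 to 0.025, Hspa5 -0.43 to 0.096, Srebf2 -0.12 to 0.43, Plvap -0.026 to 0.20, Creb3l1 -0.12 to 0.40, Herpud1 -0.29 to 0.26, Eno1 -0.23 to 0.080, Hes1 -0.085 to 0.81, Egfl7 -0.21 to 0.60 and Aldoa -0.048 to 0.25. For lists they were proliferation -0.14 to 0.83, p53 -0.016 to 0.29, FOXO -0.21 to 0.096, inflammatory -0.43 to 0.43, interferon -0.040 to 0.82, immediate early -0.19 to 0.22, unfolded protein response -0.00084 to 0.081, cholesterol -0.12 to 0.16, cilium -0.11 to 0.036, hypoxia -0.16 to 0.0032, ductal -0.022 to 0.13 and endothelial -0.39 to 0.20. No named gene past the threshold and, apart from the acinar and mitochondrial lists with the acinar covariate, no list past it changed sign.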

Other observations

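The tests of other splits, GC content, transcripts of other cell types and length bias in the marker lists were fixed before their results were seen; the tests of single-library bias, of a lower ductal share, of carry-over and of chromosome position were chosen only after the pattern was seen. Genes outside the naming rule in this part were chosen after their values were seen. No list of macrophage genes was fixed or tested beyond the immune markers, which did not pass without mouse 6 (median 0.24) and took 1.08% of the counts in mouse 6 against 0.484% and 0.367% in mice 9 and 10. The complement genes C1qa, C1qb and C1qc stood at 446 ± 275, 685 ± 478 and 565 ± 388 CPM against 128 ± 51.8, 184 ± 79.8 and 160 ± 80.5 CPM (SD, n = 3; edgeR adjusted p = 0.071, 0.080 and 0.093), with all 3 libraries of Pten_Brg1_KO above all 3 of Pten_KO, and none passed. The macrophage mannose receptor Mrc1 stood at 101 ± 33.0 against 66.0 ± 17.6 CPM (adjusted p = 0.184), a smaller ratio than that of Lyve1; the difference between genes was not tested.

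With the length offset, epithelial-mesenchymal transition genes were higher as a set (median 0.61, camera adjusted p = 0.0099; adjusted p = 0.621 with an estimated correlation) and intestinal genes lower (median -1.76, camera adjusted p = 0.0079; adjusted p = 0.621 with an estimated correlation). Among transition genes S100a4 had a log2 fold change of 2.71 ± 0.71 and Tgfbi one of 1.44 ± 0.31, while Fn1 stood at -1.28 ± 0.35 and Zeb1 at -1.12 ± 0.28, all without the offset and none past the threshold. Fibroblast and immune markers were higher with the same offset (medians 0.81 and 0.77; adjusted p = 0.647 and 0.749 with an estimated correlation), and S100a4, Tgfbi and Sparc are also expressed by such cells, so the transition list does not tell a change of ductal cells from these. Ductal markers were also lower as a set (median -0.16, camera adjusted p = 0.034; adjusted p = 0.687 with an estimated correlation).

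The genotype split called 324 genes, and the highest of the other 9 splits of the 6 libraries called 0. With 10 splits, 1 of which (the real one) reached that count, no share under 0.05 can be had.

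Long genes were lower in Pten_Brg1_KO. GC content does not account for this: within each of 5 groups of GC content the correlation of length and fold change stayed at -0.45 or below. Transcripts of other cell types are argued against as the only cause, since the correlation held among the ductal markers (Spearman's rho -0.47 over 34 genes, permutation p = 0.0056, which treats genes as independent). Across libraries the slopes fell as the acinar share rose, apart from the order of mice 6 and 9. The share was 13.3%, 15.2% and 9.65% in mice 6, 9 and 10 and 9.56%, 5.04% and 1.24% in mice 11, 12 and 13. With 6 libraries a part of other cell types in the trend cannot be told apart. A length-dependent bias that differs between single libraries stays open: the slopes varied within a genotype by 0.684 of the difference between the group means, and may reflect RNA quality or amplification in low-input libraries, which no file used here measures. An effect of Brg1 loss on long genes also stays open, as a hypothesis, because all 3 slopes of one genotype lay below all 3 of the other.

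Acinar, immune and fibroblast markers were higher in Pten_Brg1_KO in camera at the preset correlation, and none of these lists passed with an estimated one (adjusted p = 0.669). Without mouse 6 the immune and fibroblast lists did not pass (medians 0.24 and 0.23). The length trend did not take up all of the difference in these 6 libraries. With the length offset the medians were 0.98 for acinar, 0.77 for immune and 0.81 for fibroblast markers. These lay above 0.5 times 1.39, 0.81 and 0.51 by more than their standard errors over genes of 0.047, 0.12 and 0.24. Those errors treat genes as independent, although the members varied together (estimated correlations 0.77, 0.92 and 0.69 without the offset). With an estimated correlation no list passed with the offset (camera adjusted p = 0.621, 0.749 and 0.647). The fibroblast markers were longer than the tested genes (median 3878 against 3247 bases), so the trend ran against their rise. A lower share of ductal cells that raises every other cell type alike stays open. Mesothelial markers (5 genes, some near the floor) differed by -1.14 ± 0.28 and endothelial ones by 0.025 ± 0.30 (log2, SE over mice). Acinar markers lay 2.96 ± 0.96 above the former and 1.798 ± 0.693 above the latter, past 2 SE. That limit was taken after a first limit of 6.25 SE for 15 pairs was not reached, so these gaps cannot decide it. Carry-over that varies between preparations of 1 genotype remains a candidate explanation for the acinar part: the acinar share varied 7.70-fold among Pten_KO mice and 1.57-fold among Pten_Brg1_KO mice, although lectin and bead selection should remove acinar cells. None of the 30 acinar markers is in another list, and whether the ductal cells themselves express them was not measured, so a change of the ductal cells or of the tissue after Brg1 loss stays open and untested.

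Several genes called with the length offset lay together on chromosomes 9 and 4. Within 25 Mb of Smarca4, a distance chosen after they were seen, 5 of 249 tested genes were called (Tmem45b, Vsig2, Olfr893, Ubash3b and Oaf, 3 lower and 2 higher). That was 2.01%, against 74 of 13989 genes (0.529%) elsewhere, Smarca4 left out. DNA linked to the Smarca4 allele stays open without a deciding value: the closest of them lay 9.81 Mb away, and 1 of 125 genes was called in the nearer 12.5 Mb against 4 of 124 in the farther (Fisher's exact p = 0.213). On chromosome 4, the 15 Mb from Zfp691 (119.2 Mb) to Cep85 (134.2 Mb) held 9 of the 79 calls other than Smarca4, among 186 tested genes (Zfp691, Cap1, Macf1, Fhl3, Tekt2, Col16a1, Sfn, Sh3bgrl3 and Cep85), and chance placement along the genome is argued against by 10000 permutations that treat genes as independent (p = 0.0002 for as many in any window). A strain segment that differs between the mice of both groups was not tested, since no genotypes are used here, and the transcriptional effect of Brg1 loss stays open for the single genes.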
